A study of Oryza sativa with 16 samples.

How the data were processed

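Total RNA of rice seedlings (variety IR64, 7 days old) given water or 1 of 6 hormones for 3 h was extracted with TRI reagent, and 5 µg was turned into biotinylated cRNA and hybridized to the Affymetrix rice array, per the labels' protocols. The labels gave 16 arrays in 8 groups of 2 biological replicates: 2 sets of water controls and 1 group for each of IAA and BAP at 50 µM and ABA, ACC, SA and JA at 100 µM. Nothing in the labels tied a hormone to a control set.

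The deposited values are 1 number per probe set and array, which the authors made with GCRMA, per the submitters' processing notes. GCRMA corrects the background, normalizes between arrays and summarises probes, and its version and settings are not given in the sources used here. The log base was not stated, and the deposited values were taken as log2 from their range. Background correction compresses or spreads values near the bottom of the scale, so folds of genes that were near it in 1 group depend on that step. Of 57381 probe sets, 123 were Affymetrix controls and 64 reporter probe sets, both left out of the tests, and 57194 were rice probe sets. Of these 22436 had 1 gene in the platform annotation, 95 had several and 34663 had none given there. No gene was named from a probe set with several. The 22436 probe sets stood for 17905 genes, of which 17905 were found in the RefSeq gene table (assembly ASM3414082v1) and 2448 had a name other than a locus or clone identifier. No coordinates were used, since the array and this assembly differ.

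A probe set was tested if its log2 value was above 5 in at least 2 of the 16 arrays, which left 24100. A linear model was fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over 7 groups, with the 4 control arrays as 1 group and 9 residual degrees of freedom. Each hormone was compared with the control arrays and with the mean of the other 5 hormones, two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The control sets were compared in a fit with 8 groups and 8 residual degrees of freedom. The design, this filter and the alternatives were fixed before the data were examined, except those named here as added. The number of arrays limits the precision.

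Gene lists were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (the highest mean over the arrays) and adjustment over 240 tests of lists and hormones, and again with an estimated correlation and with fry. Lists with fewer than 3 measured genes were not tested. The 43 lists had been written as patterns on gene descriptions, which the reference tables did not hold. They were written again as gene symbols, some added and some dropped, after the format of the tables and the spike-in controls had been seen but before any gene's change was. The lists in the form used were therefore not fixed before the data were examined.

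Named genes followed a rule fixed in advance. It took the 10 largest rises and 10 largest falls per hormone among probe sets with 1 named gene, adjusted p under 0.05, at least 2-fold change and both treated arrays outside the range of the 4 control arrays, and allowed up to 4 members per list with the smallest p, called or not. All 109 combinations of hormone and gene of the first part were named. The second part alone allowed 890, of which 291 had an adjusted p under 0.05, and 67 of these 291 were named, chosen after their values were seen. The rule asked for a gene description, and a name other than a locus or clone identifier was used in its place. Genes named for the control sets and in the closing observations were chosen after their values were seen.

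Spike-in controls (36 poly-A and 27 hybridization probe sets) were compared between arrays to look for batches, as were the 3' and 5' probe sets of actin, GAPDH and cyclophilin, which report on RNA quality. Because they separated control1, IAA and BAP from the other arrays, fits against the control set of the same spike-in group, fits of that group's arrays alone, and the spike-in group as a block were added after the data had been seen. Overlaps of calls were set beside those of independent lists and beside 20 simulations of arrays that did not differ from the control set of their spike-in group, and were repeated with the control sets split. Alternatives fixed in advance were quantile normalization, median centring, no filter and a log2 floor of 7, other variance priors, array weights, a 2-fold minimum, each control set alone, both sets, only the treated and control arrays, the replicate number as a block, and leaving out each array in turn.

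The procedure was tested on simulated data with 200 of 24100 probe sets changed. The simulated control sets did not differ, and the noise was the spread within the 8 groups. The difference between the real control sets, which counts as spread in the main fit, was left out. The rates below are therefore for an easier setting, and recovery in the real data may be lower. Of those changed 2-fold, 71% were recovered for IAA, 78% for BAP, 71% for ABA, 74% for ACC, 71% for SA and 72% for JA, and of those changed 4-fold, 96%, 97%, 95%, 95%, 94% and 96%. False calls numbered 9 of 176, 6 of 181, 12 of 178, 11 of 180, 6 of 171 and 6 of 174. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.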

Results

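Rice (Oryza sativa subspecies indica, variety IR64) seedlings were grown in hydroponic culture for 7 days under 14 h light and 10 h dark, and then kept for 3 h in water or in a solution of 1 of 6 hormones. The auxin IAA (indole-3-acetic acid) and the cytokinin BAP (benzylaminopurine) were given at 50 µM. The other compounds, given at 100 µM, were SA (salicylic acid), JA (jasmonic acid), ABA (abscisic acid) and the ethylene precursor ACC. The design asks which transcripts respond to each hormone. Each hormone had 2 arrays, and the water controls formed 2 sets of 2 arrays, control1 and control2, which made 16 arrays on the Affymetrix rice array. Array medians lay between 2.94 and 3.09 on the log2 scale, and the replicates of a group correlated across probe sets with r between 0.987 and 0.992. No depth applies to arrays, and their number limits the precision.

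The labels did not tie a hormone to a control set, and the poly-A spike-ins split the arrays into 2 technical groups. The spike-in transcripts added to the RNA differed between their 5' and 3' probe sets by -2.01 log2 units in control1, -1.98 in IAA and -2.09 in BAP, against -0.85 in control2, -0.92 in ABA, -0.87 in ACC, -1.33 in SA and -1.32 in JA. Inside the second group the single SA and JA arrays (-1.19 to -1.45) lay apart from those of control2, ABA and ACC (-0.75 to -1.0). Control2 is therefore a less sure match for SA and JA. The hybridization spike-ins put ABA (mean 10.5) with control1 (10.3), IAA (10.4) and BAP (10.4) and not with control2 (11.8), so the batch of ABA was not settled. The 3' minus 5' differences of endogenous transcripts, a measure of RNA quality, were lower on average in control1, IAA and BAP, with single arrays of the 2 groups overlapping. That of actin was 0.89 log2 units in control1, 0.47 in IAA and 0.75 in BAP, against 1.36 in control2, 1.39 in ABA, 1.24 in ACC, 1.54 in SA and 1.3 in JA (n = 2 arrays each). Over single arrays it ran from 0.42 to 1.09 in control1, IAA and BAP and from 1.02 to 1.59 in the others, that of cyclophilin from 1.19 to 1.5 and from 1.48 to 1.94, and that of GAPDH from 0.81 to 1.07 and from 1.02 to 1.3. Changes are given as log2 values against all 4 control arrays ± SE (n = 2 treated and 4 control arrays), and "within batch" stands for the change against the control set of the same poly-A spike-in group, control1 for IAA and BAP and control2 for the other hormones. For ABA the changes against control1 alone and control2 alone are both given, and counts over several hormones that use spike-in groups place ABA with control2. All adjusted p-values are limma's with Benjamini-Hochberg adjustment, and those of gene lists come from its camera test. Counts of list members said to be adjusted over the list alone are against the 4 controls. Those within batch or against 1 control set, like the first counts of each list, were adjusted over all tested probe sets. Counts over the list alone and within batch therefore have unlike thresholds and cannot be compared directly.

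**Figure D1:**
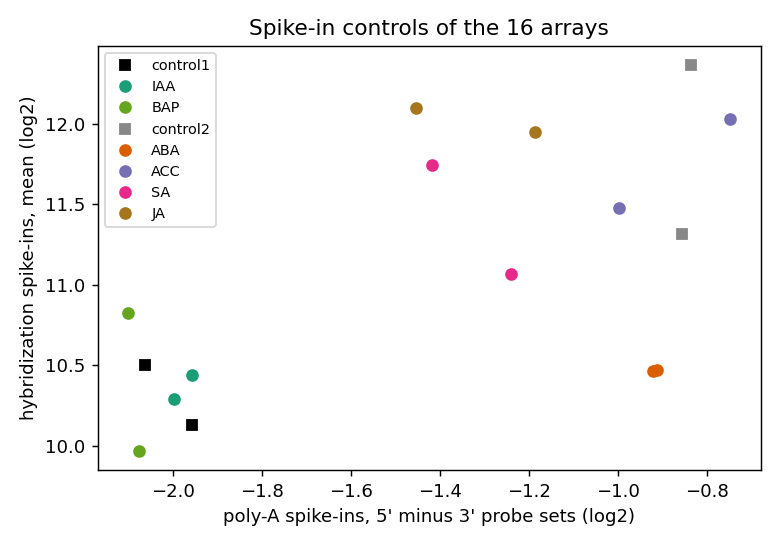
Spike-in controls of the 16 arrays, with the difference between 5' and 3' probe sets of the poly-A spike-ins (log2, x axis) against the mean of the hybridization spike-ins (log2, y axis); each point is 1 array and squares are water controls. The control1, IAA and BAP arrays lie near -2 on the x axis and the others lie to their right, with ABA low on the y axis.

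**Figure D2:**
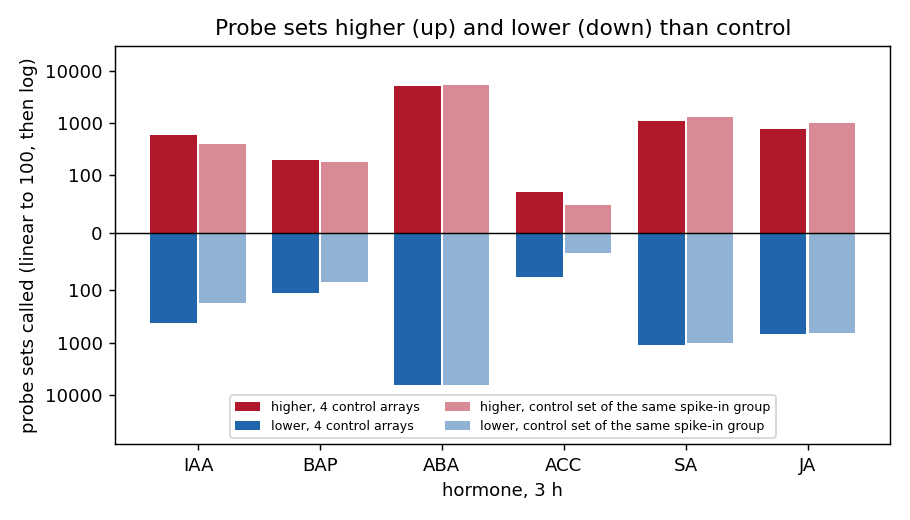
Probe sets with an adjusted p under 0.05 for each hormone (x axis), higher upward and lower downward (y axis, linear to 100 and logarithmic beyond), against the 4 control arrays (dark bars) and against the control set of the same spike-in group (light bars). The counts run from 148 for ACC to 11585 for ABA against the 4 control arrays.

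IAA raised genes of auxin signalling and auxin conjugation and lowered fewer genes. The Aux/IAA repressors IAA26 (LOC4347643) and IAA9 (LOC4331061) rose by 6.06 ± 0.15 and 5.80 ± 0.46 log2 units (within batch 6.08 and 5.06), with adjusted p = 5.17e-10 and 3.54e-05, and IAA20 (LOC4340245) by 5.28 ± 0.47 (within batch 4.42). The control mean of IAA26 was 2.25, under the log2 value of 5 used as the floor, so its size and SE depend on the lowest values. Of 25 measured Aux/IAA genes, 15 rose, 0 fell and 10 did not pass, and the list rose as a whole (adjusted p = 1.22e-16, within batch 7.86e-21). Aux/IAA genes under IAA had 17 higher and 1 lower calls adjusted over the list alone, and 14 higher and 1 lower within batch. The Aux/IAA shift was the 1 among 240 list tests that also passed with an estimated correlation (adjusted p = 0.0371).

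Among the GH3 genes, whose enzymes join auxin to amino acids, 5 of 7 rose and 0 fell, led by GH3.4 (4.92, within batch 4.35), GH3.2 (4.08, within batch 3.27), GH3-8 (3.3, within batch 2.79) and GH3.1 (2.35, within batch 2.62). GH3 genes under IAA had 5 higher and 0 lower calls adjusted over the list alone, and 5 higher and 0 lower within batch. The list rose (adjusted p = 1.94e-06, within batch 1.74e-09, and adjusted p = 0.072 with an estimated correlation). Of 16 auxin response factors, 5 rose and 0 fell, among them ARF10 (LOC4336419; 2.15, within batch 1.92), ARF15 (0.95, within batch 0.79) and ARF16 (0.9, within batch 0.85), and the list rose (adjusted p = 7.98e-06, within batch 3.41e-05, and adjusted p = 0.236 with an estimated correlation). Auxin response factor genes under IAA had 9 higher and 1 lower calls adjusted over the list alone, and 4 higher and 0 lower within batch. Genes of cytokinin metabolism gave 6 rises and 0 falls among 12, with LOGL3, of a family that activates cytokinins, at 2.51 (within batch 2.24) and CKX4, a cytokinin oxidase, at 1.42 (within batch 1.79). Cytokinin metabolism genes under IAA had 7 higher and 1 lower calls adjusted over the list alone, and 4 higher and 0 lower within batch. This list rose (adjusted p = 0.000628, within batch 0.000373, and adjusted p = 0.0833 with an estimated correlation). Of 6 glutathione S-transferases 2 rose, GST1 (2.79, within batch 3.01) and GSTU6 (1.87, within batch 2.15), and the list rose (adjusted p = 0.000916, within batch 6.94e-05, and adjusted p = 0.0937 with an estimated correlation). Glutathione S-transferase genes under IAA had 2 higher and 0 lower calls adjusted over the list alone, and 3 higher and 0 lower within batch.

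Other large rises under IAA were those of the transcription factor gene BHLH172 (4.81, within batch 4.25), the WUSCHEL-related homeobox genes WOX10 (4.78, within batch 4.75) and WOX6 (4.62, within batch 3.68), the cytochrome P450 genes CYP87A3 (4.19, within batch 3.91) and CYP734A4 (2.4, within batch 2.45), the sugar transporter gene SWEET15 (4.1, within batch 2.86), IAA24 (1.92, within batch 1.83) and NAC067 (1.79, within batch 2.07). The control means of WOX10 (2.15), CYP87A3 (2.54) and SWEET15 (3.81) lay under the floor. Falls that passed both with the 4 controls and within batch were those of ILI6, a helix-loop-helix gene (-2.3, within batch -2.31), the ammonium transporter gene AMT3-3 (-1.85, within batch -1.71), the peroxidase gene PRX112 (-1.4, within batch -1.42) and OsCASPL1U3, a Casparian strip protein-like gene (-1.3, within batch -1.08). Falls that passed against the 4 controls but not within batch were those of OsSPO11B (-1.6, within batch -1.3), AT4 (-1.45, within batch -1.18), the response regulator gene RR4 (-1.38, within batch -1.09), the aluminium transporter gene Nrat1 (-1.37, within batch -1.2), a gene listed as bHLH (-1.31, within batch -1.02), OsC3H9 (-1.28, within batch -0.9) and the cyclin gene CYCD5-1 (-1.12, within batch -0.76), with within-batch adjusted p = 0.0806, 0.0526, 0.0903, 0.0784, 0.104, 0.0743 and 0.0607. Of 33 cell cycle genes 5 fell and 0 rose, and the list fell (adjusted p = 0.000438, within batch 9.07e-05, and adjusted p = 0.273 with an estimated correlation). Cell cycle genes under IAA had 0 higher and 9 lower calls adjusted over the list alone. Adjusted over all probe sets, 0 were higher and 5 lower against the 4 controls, and 0 higher and 0 lower within batch.

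In all, 998 of 24100 tested probe sets changed under IAA, 579 higher and 419 lower, of which 517 changed at least 2-fold. Within batch 570 changed, 393 higher and 177 lower, 475 in the same direction in both comparisons, whereas control2 alone gave 7627 and a fit of the arrays of its spike-in group alone gave 268. Without IAA replicate 1 the count was 309, without IAA replicate 2 it was 523, without control1 replicate 2 it was 2304, and without control2 replicate 1 and control2 replicate 2 it was 550 and 623.

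BAP raised all 6 measured type-A response regulators, which are early cytokinin response genes that dampen cytokinin signalling. RR1 (LOC4335937) rose by 3.99 ± 0.29 log2 units (adjusted p = 2.57e-05, within batch 4.22) and RR5 (LOC4336439) by 3.74 ± 0.14 (adjusted p = 3.92e-08, within batch 3.76), and RR9 (3.13, within batch 3.55), RR6 (2.97, within batch 3.1), RR4 (2.68, within batch 2.97) and RR2 (2.21, within batch 2.66) followed. The control mean of RR5 was 2.07, under the floor, so its size and SE depend on the lowest values. Type-A response regulator genes under BAP had 6 higher and 0 lower calls adjusted over the list alone, and 6 higher and 0 lower within batch. As a list, type-A response regulator genes rose under BAP (adjusted p = 2.22e-18, within batch 1.96e-24, and adjusted p = 0.059 with an estimated correlation). Within batch the adjusted p was 0.0228 with an estimated correlation. Of 12 genes of cytokinin metabolism 4 rose and 0 fell: the cytokinin oxidase genes CKX5 (3.06, within batch 2.49), CKX3 (2.87, within batch 2.95) and CKX4 (1.51, within batch 1.88), and LOGL6 (1.95, within batch 2.28). Cytokinin metabolism genes under BAP had 5 higher and 0 lower calls adjusted over the list alone, and 4 higher and 0 lower within batch. This list rose (adjusted p = 0.000253, within batch 0.000366, and adjusted p = 0.072 with an estimated correlation).

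Other rises under BAP were those of PSK2, which encodes a precursor of the peptide phytosulfokine (2.48, within batch 2.53), and of the JAZ repressor gene JAZ5 (2.73, within batch 1.83). Of 23 genes for expansins, which loosen cell walls, 3 rose and 0 fell: EXPB11 (1.34, within batch 1.14), EXP2 (1.23, within batch 1.43) and EXPB6 (1.1; within batch 0.85, adjusted p = 0.0565). Expansin genes under BAP had 9 higher and 1 lower calls adjusted over the list alone, and 2 higher and 0 lower within batch. The list rose (adjusted p = 9.89e-05, within batch 0.0266, and adjusted p = 0.347 with an estimated correlation). Of 13 root-associated genes 3 fell and 0 rose, and the list fell (adjusted p = 0.00242, within batch 7.49e-07, and adjusted p = 0.236 with an estimated correlation): the copper transporter gene HMA5 (-1.15, within batch -0.95), PHO1-2, which acts in phosphate transfer from root to shoot (-0.89, within batch -0.8), and the silicon influx transporter gene Lsi1 (-1.5, within batch adjusted p = 0.143). Root-associated genes under BAP had 0 higher and 6 lower calls adjusted over the list alone, and 0 higher and 2 lower within batch. Further falls that also passed within batch were those of Nrat1 (-2.22, within batch -2.06), OsbZIP37 (-1.77, within batch -1.75), the trehalose phosphatase gene TPP4 (-1.6, within batch -1.43), JAMYB (-1.05, within batch -1.28) and the glutaredoxin gene GRXC7 (-1.01, within batch -1.08). Those of GLU5 (-1.96), AMT3-3 (-1.31, within batch -1.17) and OsCASPL1U3 (-1.09) kept their direction within batch but did not pass there, with adjusted p = 0.111, 0.115 and 0.0501.

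BAP changed 310 probe sets, 197 higher and 113 lower, 196 of them at least 2-fold. Within batch 263 changed, 177 higher and 86 lower, 189 in the same direction in both, whereas control2 alone gave 5788 and the arrays of its spike-in group alone 80. Without BAP replicate 1 the count was 132, without BAP replicate 2 it was 75, without control1 replicate 2 it was 568 and without control2 replicate 1 it was 190.

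Against the 4 control arrays ABA gave the highest count of the 6 hormones, 11585 probe sets, 48.1% of those tested, with 5114 higher and 6471 lower and 5227 at least 2-fold. Genes of late embryogenesis abundant (LEA) proteins and dehydrins, which accumulate in drying tissue, rose in all 9 measured cases, as did all 7 clade A protein phosphatases 2C, which are negative regulators of ABA signalling. The dehydrin gene rab25 (LOC4326935) rose by 8.26 ± 0.38 log2 units (adjusted p = 1.15e-08, control1 7.72, control2 8.8) and PP2C51 (LOC4339671) by 6.92 ± 0.14 (adjusted p = 8.37e-12, control1 6.86, control2 6.99). All 4 control arrays lay under the floor for rab25 (3.27 to 4.85) and PP2C51 (2.12 to 2.4), so their sizes and SEs depend on the lowest values. Other LEA genes were RAB16D (7.64, control1 9.05, control2 6.22), RAB16B (7.28, control1 8.14, control2 6.43), RAB16C (7.17, control1 8.61, control2 5.73) and EM (7.13). EM rose by 11.79 against control1 and by 2.47 against control2. Its mean was 2.59 in control1, under the log2 value of 5 used as the floor, and 11.92 in control2, so the sizes against control1 and all 4 controls depend on the lowest values. LEA genes under ABA had 9 higher and 0 lower calls adjusted over the list alone, 9 higher and 0 lower against control1, and 9 higher and 0 lower against control2. As a list, LEA genes rose under ABA (adjusted p = 0.000101, against control1 3.92e-06, against control2 3.41e-05, and adjusted p = 0.236 with an estimated correlation). Clade A phosphatase genes under ABA had 7 higher and 0 lower calls adjusted over the list alone, 7 higher and 0 lower against control1, and 7 higher and 0 lower against control2. As a list, clade A phosphatase genes rose under ABA (adjusted p = 9.89e-05, against control1 9.1e-05, against control2 1.25e-06, and adjusted p = 0.391 with an estimated correlation). Further phosphatase genes that rose were PP2C30 (6.11, control1 5.01, control2 7.21), PP2C68 (5.67, control1 4.39, control2 6.96) and OsPP2C08 (4.73, control1 4.34, control2 5.12).

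Of 3 genes of ABA metabolism 3 rose, with ABA8OX2 (4.37, control1 3.81, control2 4.94) and ABA8OX1 (2.64, control1 2.49, control2 2.79), which encode ABA 8'-hydroxylases that inactivate the hormone. ABA metabolism genes under ABA had 3 higher and 0 lower calls adjusted over the list alone, 3 higher and 0 lower against control1, and 2 higher and 0 lower against control2. As a list, ABA metabolism genes rose under ABA (adjusted p = 0.0181, against control1 0.0186, against control2 0.0222, and adjusted p = 0.236 with an estimated correlation). Of 42 genes of heat shock proteins and factors 17 rose and 2 fell, led by HSP18.6 (7.64, control1 7.62, control2 7.67), HSFA6B (6.58, control1 6.27, control2 6.89) and the disaggregase gene CLPB1 (3.59, control1 3.67, control2 3.5). Heat shock genes under ABA had 16 higher and 2 lower calls adjusted over the list alone, 13 higher and 4 lower against control1, and 20 higher and 3 lower against control2. As a list, heat shock genes rose under ABA (adjusted p = 0.0104, against control1 0.0398, against control2 0.00269, and adjusted p = 0.426 with an estimated correlation). Of 6 genes of senescence and chlorophyll breakdown 4 rose and 1 fell, with the chlorophyll b reductase gene NYC1 (3.18, control1 3.03, control2 3.32) and the stay-green gene SGR (3.06, control1 2.81, control2 3.31). Senescence genes under ABA had 4 higher and 1 lower calls adjusted over the list alone, 4 higher and 0 lower against control1, and 4 higher and 0 lower against control2. As a list, senescence genes rose under ABA (adjusted p = 0.0132, against control1 0.0227, against control2 0.0202, and adjusted p = 0.239 with an estimated correlation). SWEET15 (8.22, control1 6.98, control2 9.47), the peroxiredoxin gene R1C-Prx (8.13, control1 7.68, control2 8.58), OsC3H10 (7.14, control1 7.18, control2 7.1) and the homeobox gene HOX24 (7.41) also rose. HOX24 rose by 4.51 against control1 and by 10.31 against control2, where its mean lay under the floor (2.77), so the sizes against control2 and all 4 controls depend on the lowest values.

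Many groups fell under ABA. Of 25 ribosomal protein genes 21 fell and 0 rose. Ribosomal protein genes under ABA had 0 higher and 22 lower calls adjusted over the list alone, 0 higher and 21 lower against control1, and 1 higher and 19 lower against control2. As a list, ribosomal protein genes fell under ABA (adjusted p = 8.94e-05, against control1 6.79e-06, against control2 0.000715, and adjusted p = 0.426 with an estimated correlation). Of 33 cell cycle genes 18 fell and 2 rose. Cell cycle genes under ABA had 3 higher and 20 lower calls adjusted over the list alone, 2 higher and 19 lower against control1, and 2 higher and 16 lower against control2. As a list, cell cycle genes fell under ABA (adjusted p = 0.00109, against control1 0.0045, against control2 0.00189, and adjusted p = 0.309 with an estimated correlation). Cell cycle genes that fell included the DNA replication genes MCM4 (-3.15, control1 -3.17, control2 -3.12), PCNA (-3.0, control1 -2.96, control2 -3.04) and OsMCM6 (-2.91, control1 -2.76, control2 -3.05). Of 13 root-associated genes 11 fell and 0 rose, with the silicon transporter genes Lsi2 (-6.79, control1 -6.3, control2 -7.28) and Lsi1 (-2.35, control1 -2.06, control2 -2.65), the iron transporter gene IRT1 (-3.96, control1 -5.06, control2 -2.86) and the manganese transporter gene NRAMP5 (-2.74, control1 -2.91, control2 -2.57). Root-associated genes under ABA had 0 higher and 11 lower calls adjusted over the list alone, 0 higher and 12 lower against control1, and 0 higher and 9 lower against control2. As a list, root-associated genes fell under ABA (adjusted p = 0.00196, against control1 0.000919, against control2 0.0045, and adjusted p = 0.236 with an estimated correlation). Of 23 expansin genes 14 fell and 1 rose, with EXPB11 (-3.85, control1 -4.04, control2 -3.65) and EXP2 (-3.84, control1 -3.64, control2 -4.03). Expansin genes under ABA had 1 higher and 15 lower calls adjusted over the list alone, 1 higher and 15 lower against control1, and 3 higher and 13 lower against control2. As a list, expansin genes fell under ABA (adjusted p = 0.00228, against control1 0.0003, against control2 0.031, and adjusted p = 0.426 with an estimated correlation). Of 11 shoot-associated photosynthesis genes 7 fell and 0 rose, among them PORA, which encodes an enzyme of chlorophyll synthesis (-4.24, control1 -4.74, control2 -3.73). Photosynthesis genes under ABA had 0 higher and 8 lower calls adjusted over the list alone, 0 higher and 7 lower against control1, and 0 higher and 8 lower against control2. As a list, photosynthesis genes fell under ABA (adjusted p = 0.0179, against control1 0.0428, against control2 0.019, and adjusted p = 0.635 with an estimated correlation). Of 15 phenylpropanoid genes 10 fell and 1 rose, with CAD8A (-2.97, control1 -2.76, control2 -3.18) and 4CL (-1.89, control1 -1.4, control2 -2.39). Phenylpropanoid genes under ABA had 1 higher and 11 lower calls adjusted over the list alone, 2 higher and 9 lower against control1, and 1 higher and 11 lower against control2. As a list, phenylpropanoid genes fell under ABA (adjusted p = 0.0213, against control1 0.0688, against control2 0.00534, and adjusted p = 0.472 with an estimated correlation).

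Further falls under ABA were those of the allene oxide synthase gene AOS4 (-5.39, control1 -4.78, control2 -6.0), which acts in jasmonate synthesis, the zinc transporter gene ZIP3 (LOC4336971; -4.76, control1 -4.48, control2 -5.03), the urea transporter gene DUR3 (-4.58, control1 -4.78, control2 -4.37), PRX112 (-4.51, control1 -4.53, control2 -4.49), GLU14 (-4.03, control1 -3.86, control2 -4.21), ILI6 (-4.01, control1 -4.02, control2 -3.99) and CSFL8 (-3.98, control1 -4.25, control2 -3.71). The response regulator genes RR9 (-3.55, control1 -3.13, control2 -3.97) and RR2 (-3.32, control1 -2.88, control2 -3.77) fell too. Against control2 alone 11911 probe sets changed, 5230 higher and 6681 lower, and against control1 alone 12748, with 9008 called against both sets. Of the lists named for ABA, phenylpropanoid synthesis did not pass against control1 alone (adjusted p = 0.0688), while those of LEA proteins (3.92e-06) and clade A phosphatases (9.1e-05) and the other lists did.

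Against the 4 control arrays ACC changed the fewest probe sets, 148, with 71 higher and 77 lower and 93 at least 2-fold. The ethylene receptor gene ETR2 (LOC4335058) rose by 1.43 ± 0.11 log2 units (adjusted p = 0.00019, within batch 1.42), as the 1 riser among 6 genes of ethylene receptors and signalling, of which 0 fell. Ethylene signalling genes under ACC had 2 higher and 2 lower calls adjusted over the list alone, and 1 higher and 0 lower within batch. That list did not pass as a whole (adjusted p = 0.198, within batch 0.121, and adjusted p = 0.426 with an estimated correlation). HIRL2 (2.16, within batch 2.04), LPR1 (2.11, within batch 2.14) and the expansin gene EXP6 (0.8, within batch 0.81) also rose. The pectin methylesterase inhibitor gene PMEI8 (-2.8), the expansin gene EXP1 (-1.44), LOGL3 (-1.35), the cyclin gene CYCP2-1 (-1.22), the heat shock factor gene HSFA2B (-1.12) and the aquaporin gene PIP2-2 (-1.07) were lower against the 4 controls. Within batch they were lower too but did not pass, with adjusted p = 0.0664, 0.063, 0.0535, 0.0639, 0.0535 and 0.11. Of 19 aquaporin genes 1 fell, and the list fell (adjusted p = 0.00341, within batch 0.0453, and adjusted p = 0.426 with an estimated correlation). Aquaporin genes under ACC had 0 higher and 2 lower calls adjusted over the list alone. Adjusted over all probe sets, 1 was lower against the 4 controls, and 0 were higher and 0 lower within batch.

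Of the clade A phosphatases 7 of 7 did not pass singly under ACC, while the list lay lower (adjusted p = 0.00152, within batch 0.0202, and adjusted p = 0.472 with an estimated correlation). Clade A phosphatase genes under ACC had 0 higher and 5 lower calls adjusted over the list alone. Adjusted over all probe sets, 0 were higher and 0 lower within batch. All 25 Aux/IAA genes missed the threshold singly, while that list lay lower (adjusted p = 0.00293, within batch 0.0279, and adjusted p = 0.309 with an estimated correlation). Aux/IAA genes under ACC had 0 higher and 2 lower calls adjusted over the list alone, and 0 higher and 1 lower within batch. Within batch ACC changed 82 probe sets, 47 higher and 35 lower, 53 in the same direction in both, whereas control1 alone gave 5767 and the arrays of its spike-in group alone 20. Without ACC replicate 1 and ACC replicate 2 the count was 15 and 33, without control1 replicate 1 and control1 replicate 2 it was 47 and 70, and without control2 replicate 1 and control2 replicate 2 it was 455 and 292.

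SA raised heat shock genes, glutathione S-transferase genes and phosphate response genes. HSP18.1 (LOC4332361) rose by 5.97 ± 0.43 log2 units (adjusted p = 1.09e-05, within batch 6.3) and GST1 (LOC4334347) by 4.01 ± 0.25 (adjusted p = 3.09e-06, within batch 3.79). Of 42 genes of heat shock proteins and factors 9 rose and 1 fell, with HSP26.7 (4.2, within batch 4.19), HSP23.2 (3.65, within batch 3.81), HSP17.4 (3.46, within batch 4.12), HSP18.6 (2.75, within batch 2.78) and CLPB1 (2.34, within batch 2.25). Heat shock genes under SA had 15 higher and 2 lower calls adjusted over the list alone, and 11 higher and 1 lower within batch. As a list, heat shock genes rose under SA (adjusted p = 1.79e-05, within batch 1.25e-06, and adjusted p = 0.236 with an estimated correlation). Of 6 glutathione S-transferases 3 rose, including GSTU6 (2.53, within batch 2.25) and GSTZ5 (2.04, within batch 1.56). Glutathione S-transferase genes under SA had 3 higher and 0 lower calls adjusted over the list alone, and 3 higher and 0 lower within batch. As a list, glutathione S-transferase genes rose under SA (adjusted p = 0.000628, within batch 9.07e-05, and adjusted p = 0.0904 with an estimated correlation). The WRKY transcription factor genes WRKY76 (3.0, within batch 2.77) and WRKY62 (2.56, within batch 2.01), the esterase gene Pir7b (3.66, within batch 2.51), SAP17 (2.83, within batch 2.32) and the oxophytodienoate reductase gene OPR1 (2.65, within batch 3.07) rose as well. Of 12 phosphate response genes 3 rose and 0 fell, with SPX5 (2.32, within batch 1.57) and the phosphate transporter gene PHT1-8 (1.31, within batch 1.61). Phosphate response genes under SA had 4 higher and 0 lower calls adjusted over the list alone, and 2 higher and 0 lower within batch. As a list, phosphate response genes rose under SA (adjusted p = 0.00177, within batch 0.0157, and adjusted p = 0.236 with an estimated correlation). Of 7 genes of salicylate signalling 1 rose, NH2, a homologue of the SA regulator NPR1 (0.89, within batch 0.86). Salicylate signalling genes under SA had 2 higher and 0 lower calls adjusted over the list alone, and 1 higher and 0 lower within batch. That list did not pass (adjusted p = 0.373, within batch 0.503, and adjusted p = 0.665 with an estimated correlation), with a median of -0.04 below 0 and a mean of 0.17 and a test direction above it.

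Cell cycle, cytokinin response, root-associated and expansin genes fell under SA. Of 33 cell cycle genes 10 fell and 0 rose, with ORC3 (-1.61, within batch -1.59), MCM4 (-1.28, within batch -1.25) and PCNA (-1.21, within batch -1.25). Cell cycle genes under SA had 0 higher and 13 lower calls adjusted over the list alone, and 0 higher and 8 lower within batch. As a list, cell cycle genes fell under SA (adjusted p = 6.82e-06, within batch 1.47e-05, and adjusted p = 0.175 with an estimated correlation). Of 6 type-A response regulators 4 fell, with RR4 (-1.89, within batch -2.18) and RR1 (-1.58, within batch -1.81). For RR1 the SA arrays (3.53 and 3.61) and all control arrays except control2 replicate 2 (6.0) lay under the floor. The sizes of its fall therefore depend on the lowest values and on that array. Type-A response regulator genes under SA had 0 higher and 5 lower calls adjusted over the list alone, and 0 higher and 5 lower within batch. As a list, type-A response regulator genes fell under SA (adjusted p = 0.000628, within batch 0.00014, and adjusted p = 0.347 with an estimated correlation). Of 13 root-associated genes 5 fell and 0 rose, with Lsi1 (-1.2, within batch -1.5) and the nitrate transporter gene NRT2.3 (-2.16, within batch adjusted p = 0.06). Root-associated genes under SA had 0 higher and 8 lower calls adjusted over the list alone, and 0 higher and 4 lower within batch. As a list, root-associated genes fell under SA (adjusted p = 0.000232, within batch 0.00275, and adjusted p = 0.154 with an estimated correlation). Of 23 expansin genes 7 fell and 1 rose, with EXPB2 (-2.0, within batch -1.56) and EXPB11 (-1.85, within batch -1.66). Expansin genes under SA had 1 higher and 9 lower calls adjusted over the list alone, and 1 higher and 6 lower within batch. As a list, expansin genes fell under SA (adjusted p = 7.66e-05, within batch 0.0219, and adjusted p = 0.346 with an estimated correlation). Of 25 ribosomal protein genes 6 fell against the 4 controls. Ribosomal protein genes under SA had 1 higher and 19 lower calls adjusted over the list alone. Adjusted over all probe sets, 6 were lower against the 4 controls, and 1 was higher and 0 lower within batch. As a list, ribosomal protein genes fell under SA (adjusted p = 5.5e-06, within batch 0.00086, and adjusted p = 0.377 with an estimated correlation). DUR3 (-3.43, within batch -3.23), PRX112 (-2.73, within batch -2.71), AMT3-3 (-2.29, within batch -2.43), the glutaredoxin genes GRXC15 (-2.76, within batch -2.92) and GRXC10 (-2.47, within batch -2.65), OsSWEET2b (-2.05, within batch -1.5), PORA (-1.98, within batch -1.48) and the laccase gene LAC10 (-1.98, within batch -2.67) fell too.

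SA changed 2217 probe sets, 1091 higher and 1126 lower, 855 of them at least 2-fold. Within batch 2325 changed, 1311 higher and 1014 lower, 1469 in the same direction in both, and control1 alone gave 6908. Without SA replicate 1 the count was 432, without SA replicate 2 it was 1116 and without control1 replicate 1 it was 1405.

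JA raised genes of its own signalling, of a joint list of lipoxygenases and jasmonate synthesis, and of diterpenoid phytoalexin synthesis. JAZ5 (LOC4335698) rose by 5.20 ± 0.55 log2 units (adjusted p = 0.000326, within batch 6.09) and JAZ13 (LOC4348531) by 3.80 ± 0.32 (adjusted p = 5.67e-05, within batch 3.82). Of 15 TIFY/JAZ genes, which include the repressors of jasmonate signalling, 9 rose and 0 fell, among them JAZ11 (2.54, within batch 2.85) and JAZ6 (1.45, within batch 1.61). TIFY/JAZ genes under JA had 11 higher and 0 lower calls adjusted over the list alone, and 9 higher and 0 lower within batch. As a list, TIFY/JAZ genes rose under JA (adjusted p = 6.2e-11, within batch 4.68e-12, and adjusted p = 0.154 with an estimated correlation). Of 17 genes of lipoxygenases and jasmonate synthesis 8 rose and 0 fell, with LOX1.1 (3.48, within batch 3.31) and OPR10 (2.24, within batch 1.9). Lipoxygenase and jasmonate synthesis genes under JA had 13 higher and 1 lower calls adjusted over the list alone, and 11 higher and 0 lower within batch. As a list, lipoxygenase and jasmonate synthesis genes rose under JA (adjusted p = 6.24e-09, within batch 2.54e-11, and adjusted p = 0.0833 with an estimated correlation). Because the list mixes both kinds of gene, its rise alone does not show a rise of jasmonate synthesis. Of 12 diterpenoid phytoalexin genes 5 rose and 0 fell: KSL4 (2.58, within batch 2.89), CPS4 (2.55, within batch 2.58), CYP76M5 (2.18, within batch 2.6) and CYP99A2 (1.94, within batch 1.88) were among them. With only the treated and control arrays CPS4 passed, while KSL4, CYP76M5 and CYP99A2 did not. Diterpenoid phytoalexin genes under JA had 6 higher and 0 lower calls adjusted over the list alone, and 4 higher and 0 lower within batch. As a list, diterpenoid phytoalexin genes rose under JA (adjusted p = 5.5e-06, within batch 4.77e-05, and adjusted p = 0.371 with an estimated correlation). Of 6 glutathione S-transferases 2 rose, with GST1 (2.43, within batch 2.21). Glutathione S-transferase genes under JA had 5 higher and 0 lower calls adjusted over the list alone, and 3 higher and 0 lower within batch. As a list, glutathione S-transferase genes rose under JA (adjusted p = 8.29e-05, within batch 4.61e-05, and adjusted p = 0.072 with an estimated correlation). Of 15 phenylpropanoid genes 3 rose, with CAD8A (1.94, within batch 1.74) and 4CL5 (1.41, within batch 1.46). Phenylpropanoid genes under JA had 3 higher and 1 lower calls adjusted over the list alone, and 2 higher and 0 lower within batch. As a list, phenylpropanoid genes rose under JA against the 4 controls (adjusted p = 0.00658). They did not pass within batch (adjusted p = 0.338) or with an estimated correlation (adjusted p = 0.418).

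Other rises under JA were those of JAMYB, a jasmonate-induced MYB gene (2.57, within batch 2.8), NH1, the rice NPR1 homologue (1.83, within batch 2.18), and SGR (1.81, within batch 2.06). GLP2 (2.34) and CRSH2 (2.33) rose against the 4 controls. Within batch they were higher too but did not pass, with adjusted p = 0.0517 and 0.128. Of 33 cell cycle genes 9 fell and 0 rose, with PCNA (-1.15, within batch -1.19) and MCM2 (-0.96, within batch -0.89). Cell cycle genes under JA had 0 higher and 9 lower calls adjusted over the list alone, and 0 higher and 8 lower within batch. As a list, cell cycle genes fell under JA (adjusted p = 0.000154, within batch 0.000479, and adjusted p = 0.236 with an estimated correlation). Of 6 type-A response regulators 3 fell, with RR4 (-1.44, within batch -1.74) and RR1 (-1.34, within batch -1.58). For RR1 the JA arrays (3.99 and 3.62) and all control arrays except control2 replicate 2 lay under the floor, so the size depends on the lowest values. Type-A response regulator genes under JA had 0 higher and 4 lower calls adjusted over the list alone, and 0 higher and 3 lower within batch. As a list, type-A response regulator genes fell under JA (adjusted p = 0.00543, within batch 0.00107, and adjusted p = 0.426 with an estimated correlation). Of 23 expansin genes 4 fell, with EXP29 (-2.94, within batch -1.94) and EXPB7 (-2.75, within batch -2.94). Expansin genes under JA had 0 higher and 8 lower calls adjusted over the list alone, and 0 higher and 3 lower within batch. As a list, expansin genes fell under JA against the 4 controls (adjusted p = 0.00242). They did not pass within batch (adjusted p = 0.146) or with an estimated correlation (adjusted p = 0.426). Without hormone this list was lower in control2 than in control1 (adjusted p = 0.00748), so the fall against the 4 controls may reflect the control sets. Falls were also found for NRT2.3 (-3.63, within batch -2.75), the glutaredoxin genes GRXC1 (-2.54, within batch -2.77) and GRXC10 (-1.66, within batch -1.84), OsC3H23 (-2.13, within batch -1.83), the aquaporin gene PIP2-5 (-1.67, within batch -1.27), GLU5 (-1.61, within batch -2.22) and BHLH003 (-1.59, within batch -1.65). The fall of GLU5 did not pass against control1 alone or with the replicate number as a block. BHLH172 fell against the 4 controls (-1.79) and was lower within batch too, but did not pass there (adjusted p = 0.099).

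JA changed 1436 probe sets, 744 higher and 692 lower, 662 of them at least 2-fold. Within batch 1639 changed, 975 higher and 664 lower, 1007 in the same direction in both, and control1 alone gave 5759. Without JA replicate 2 the count was 243.

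**Figure D3:**
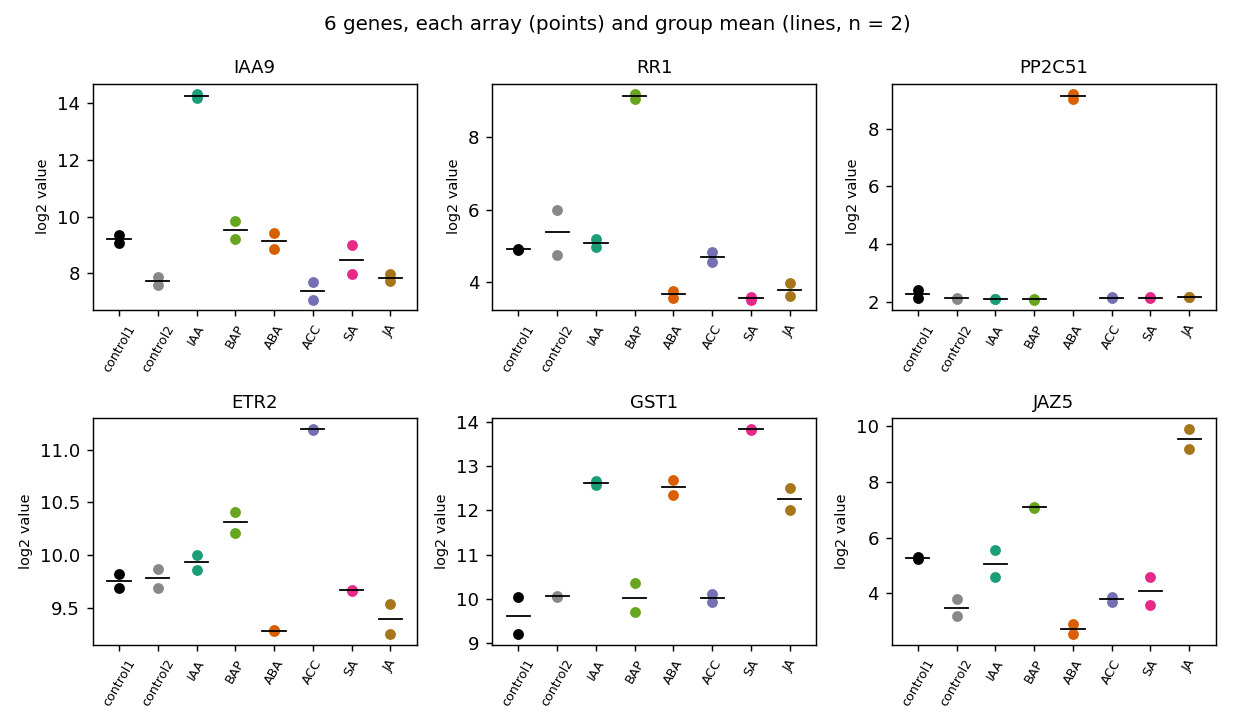
Log2 values (y axis) of 6 genes in each of the 16 arrays by group (x axis); points are arrays and lines are group means (n = 2). IAA9 was highest under IAA, RR1 under BAP, PP2C51 under ABA, ETR2 under ACC, GST1 under SA and JAZ5 under JA.

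Named genes made up 176 hormone and gene combinations (136 genes), 109 of them the largest rises and falls, and 67 chosen as list members after their values were seen, all of which had passed against the 4 controls. The numbers that passed here therefore do not measure how often list members respond. Within batch, with control2 for ABA, 89 of the 109 and 65 of the 67 also passed, 154 in all, with the same sign, among them 4 of the 10 of ACC. Of all 291 called list members from which the 67 could be taken, 238 also passed within batch in the same direction. Of the 26 of BAP, 13 passed without BAP replicate 1 and 10 without BAP replicate 2. Of the 10 of ACC, 3 passed without ACC replicate 1, 2 without ACC replicate 2 and 3 without control1 replicate 1, and of the 32 of JA, 16 passed without JA replicate 2. In 17 of the rises the control mean lay under the log2 value of 5 used as the floor. These were IAA26, WOX10, CYP87A3 and SWEET15 under IAA, RR5, CKX3, LOGL6 and JAZ5 under BAP, rab25, PP2C51, OsC3H10 and SWEET15 under ABA, HSP26.7, HSP23.2 and SPX5 under SA, and JAZ5 and CYP76M5 under JA. In 5 further rises (WOX6 under IAA, RR1 under BAP, and R1C-Prx, HOX24 and EM under ABA) the mean of 1 control set alone did, and in 14 of the falls the treated mean did. The size of all those changes depends on the lowest values of the authors' processing. Other probe sets of these genes, counted once for each hormone under which the gene was named, gave 12 combinations. Of these 9 were called in the same direction and 0 in the opposite one. In 10 of the 136 genes (IAA24, ARF16, CYP87A3, GST1, RR1, TPP4, PP2C51, PCNA, HIRL2 and JAZ11) 1 control array stood apart from the other 3.

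Each hormone was also set against the mean of the other 5, without the control arrays. This comparison also carries the difference between the spike-in groups. It does so most for IAA and BAP, whose other hormones lay mostly in the other group. The mean of the other 5 also holds their own responses, and against control ABA changed 11585 probe sets and ACC 148. A difference counted for another hormone may therefore be a response to ABA. The same holds for ACC, SA and JA against their own spike-in group, which includes ABA. ABA differed from the other hormones in 11951 probe sets, IAA in 6126, BAP in 5213, JA in 3067, ACC in 2853 and SA in 1411. Doses were 50 µM for IAA and BAP and 100 µM for the rest. With the spike-in group as a block these counts were 12378 for ABA, 1154 for IAA, 1726 for BAP, 3168 for JA, 2135 for ACC and 1460 for SA. Against the other hormones of the same spike-in group alone they were 12201 for ABA, 5522 for ACC, 1878 for SA and 5228 for JA, and 760 between IAA and BAP. Of the probe sets changed against control, 10535 of ABA, 810 of IAA, 271 of BAP, 981 of JA, 128 of ACC and 876 of SA also differed from the other hormones in the same direction. Of those changed within batch, 10830 of 11911 of ABA, 310 of 570 of IAA, 207 of 263 of BAP, 1101 of 1639 of JA, 71 of 82 of ACC and 967 of 2325 of SA did so with the spike-in group as a block. Leaving out replicate 1 or replicate 2 of the hormone itself gave 1210 or 2757 for IAA, 2311 or 1105 for BAP, 519 or 997 for ACC, 285 or 667 for SA and 1845 or 758 for JA, and without ABA replicate 2 the count was 7470.

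The 2 control sets, which had no hormone, differed in 5087 of 24100 probe sets, with 2216 higher and 2871 lower in control2 and 1750 at least 2-fold. The genes named here were chosen after their values were seen. Higher in control2 were the LEA genes EM (9.32 ± 0.46, n = 2 arrays per set) and RAB16C (2.88 ± 0.61), the dehydrin gene RAB21 (5.38 ± 1.23), and the clock gene PCL1 (3.67 ± 0.53), with adjusted p = 1.21e-06, 0.00719, 0.0105 and 0.00102. Of 9 genes of LEA proteins and dehydrins 3 were higher and 2 lower in control2, Dhn1 (-2.07) and rab25 (-1.08, under the floor in both sets). That list did not pass (adjusted p = 0.229; adjusted p = 0.807 with an estimated correlation). Lower in control2 were GLU15 (-7.29), a pyruvate decarboxylase gene (-6.76), HOX24 (-5.8), the hemoglobin genes NSHB2 (-4.77) and NSHB1 (-4.6), and the homeobox gene WOX11 (-4.03), with adjusted p = 0.000475, 0.000632, 0.000139, 8.94e-05, 0.000188 and 6.02e-05. EM in control1 and GLU15, the pyruvate decarboxylase gene and HOX24 in control2 lay under the floor, so the sizes of those differences depend on the lowest values. The 3' minus 5' differences in control1 and control2 were 0.89 and 1.36 for actin, 1.42 and 1.7 for cyclophilin and 1.05 and 1.06 for GAPDH. Of 5 hypoxia-associated genes 3 were lower in control2 (adjusted p = 0.0107; adjusted p = 0.224 with an estimated correlation). Of 7 clade A phosphatases 6 were lower in control2 (adjusted p = 0.00104; adjusted p = 0.451 with an estimated correlation), of 23 expansins 9 (adjusted p = 0.00748; adjusted p = 0.224 with an estimated correlation) and of 25 ribosomal proteins 7 (adjusted p = 0.00304; adjusted p = 0.358 with an estimated correlation). Among 7 clock genes CCA1 was lower in control2 (-2.48), PRR95 (1.48), PRR1 (1.15), PRR37 (0.65) and GI (0.46) were higher, and PRR73 did not pass (0.11). The clock list did not pass (adjusted p = 0.0598). Without control1 replicate 1, control1 replicate 2 and control2 replicate 2 the number of differing probe sets was 2853, 1752 and 2040. The set and the spike-in group cannot be told apart here.

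Overlaps between hormones were counted over the same 24100 probe sets, with all comparisons sharing the 4 control arrays. ABA and SA shared 672 probe sets called higher in both and 964 called lower in both, with 102 in opposite directions, against 232, 302 and 532 for independent lists. SA and JA shared 170 higher and 231 lower (33.7 and 32.3 for independent lists), with 54 opposite (66.1). IAA and SA shared 146 higher and 67 lower (26.2 and 19.6), and BAP and SA had 65 in opposite directions (14.3 for independent lists) with 27 in the same one. In 20 simulations of hormone arrays that did not differ from the control set of their spike-in group, the highest same-direction count of a pair was 0. No hormone had more than 1 call in any of them, so this value says nothing about the overlap of longer lists. With control1 for one hormone and control2 for the other, which sets hormones against the controls of the other spike-in group too, the mean same-direction count was 2189.5 for ABA and SA (1168 for independent lists of those lengths) and 486.5 for SA and JA (251). For IAA and SA the 2 splits lay on opposite sides of independent lists, with 181 against 28.8 where each hormone had the control set of its own spike-in group, and 375 against 1078 where each had the other set. For BAP and SA they gave 26 against 13.2, and 132 against 825. Within batch the same-direction counts were 1747, 523, 181 and 26, against 566, 81, 28.8 and 13.2 for independent lists. The counts in opposite directions were then 126, 55, 15 and 60, against 583, 77.1, 26.2 and 12.1. With ABA set against control1 and SA against control2, ABA and SA shared 1488 in the same direction (605 for independent lists). Across probe sets, which are not independent replicates, the changes correlated with r = 0.454 for ABA and SA (simulated 0.779) and 0.421 for SA and JA (simulated 0.78). Within batch r was 0.503 and 0.41, and both hormones of each pair shared control2. With the controls split r was 0.342 and 0.176 for ABA and SA and 0.0765 and 0.0355 for SA and JA. The covariance was 0.296 against a simulated 0.121 for ABA and SA, and 0.125 against 0.121 for SA and JA. With the controls split it was 0.234 and 0.152 for ABA and SA, and 0.0284 and 0.0142 for SA and JA. Of all tested probe sets 11279 were called under no hormone, 9776 under 1 and 1 under all 6.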

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

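The tests of batch, time of day, single array, weak acid, less root and more shoot were chosen after the results were seen, and only that of seed remains was planned before.

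In 10 of 136 named genes 1 of the 4 control arrays lay apart from the other 3, by a gap over the range above 0.829. Chance gives such a gap in about 1 in 20 groups of 4 values from 1 normal sample. The control arrays came from sets that differed, so that rate may not hold here. The gap over the range was 0.918 for IAA24, 0.919 for ARF16, 0.854 for CYP87A3 and 0.874 for PP2C51, with control1 replicate 2 highest. It was 0.973 for GST1 and 0.829 for TPP4 with control1 replicate 1 lowest, 0.877 for RR1 and 0.866 for PCNA with control2 replicate 2 highest, 0.930 for HIRL2 with control2 replicate 1 highest, and 0.956 for JAZ11 with control2 replicate 2 lowest.

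The 2 water control sets differed in 5087 probe sets. Of these, 95.6% differed in the same direction between the IAA and BAP arrays and the ACC, SA and JA arrays, with ABA left out. A technical batch or growth batch shared by those arrays would give this. The 7 clock genes had a median absolute difference of 1.15 log2 units, at percentile 100 of 10000 random lists, so harvest at another time of day may also contribute. The seed storage list held 1 measured gene, with a difference of 0.588, which lay between the bounds set for and against seed remains and left that open. Batch and time of day cannot be told apart here, because each control set lay in 1 spike-in group. A cause in the treatment of the seedlings was not tested.

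The 9 heat shock genes called higher under SA had a median change of 2.75 log2 units. A single outlying array was argued against, because the 7 heat shock genes called higher without SA replicate 1 lay a median of 2.77 above the 4 controls in that array, and the 8 called without SA replicate 2 a median of 3.32 in the other (lowest 1.42 and 1.43). A response common to every weak acid at 100 µM was argued against by the median of 0.0391 under JA at that dose. That value covers JA alone, and the pH of the solutions was not compared, so an effect of acidity was not excluded. ABA is an acid too. Under ABA, also at 100 µM, the median was 0.39 (control1 0.00965, control2 1.05): HSP18.6 (7.64), HSFA6B (6.58), CLPB1 (3.59) and HSFA3 (1.84) rose, HSP17.4 rose against control2 alone (1.05, adjusted p = 0.0493; control1 -0.27) and HSP17.7 fell (-0.37; against control1 adjusted p = 0.039, against control2 0.115), so a response shared by SA and ABA stays open for those that rose. A response to SA itself may remain as a hypothesis, and differences in handling of the SA seedlings were not tested.

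Of 13 root-associated genes 11 fell under ABA and 5 under SA. Less root in the harvested tissue as the whole cause would lower genes found in root alone by 1 amount. The changes under ABA ranged over 6.76 log2 units, from -6.79 for Lsi2 to -0.03. That argues against it only if the 13 genes are alike in root specificity, which was not tested. The 11 shoot-associated genes had a median of -0.597 log2 units under ABA. A fall of these genes under ABA itself would hide a gain of shoot, so this test cannot decide on more shoot. These tests used ABA alone and leave the falls under SA open. Regulation by ABA may remain as a hypothesis for the genes that fell most.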

How the results depend on the processing

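The fits by spike-in group (own arrays only, the group as a block, other hormones of the same group, and own control set for lists, overlaps and named genes) were chosen after the data were seen, and the others were planned. No named gene changed direction under any alternative run, and counts of probe sets changed against control, against the other hormones or between the control sets that are not given here stayed within 1.5 times those reported. A log2 floor near the bottom of the scale limits what the arrays could show.

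Against control, the counts of changed probe sets with at least 2-fold change were 517 of 998 for IAA, 196 of 310 for BAP, 5227 of 11585 for ABA, 93 of 148 for ACC, 855 of 2217 for SA and 662 of 1436 for JA. Control1 alone gave 570 for IAA, 5767 for ACC, 6908 for SA and 5759 for JA, and control2 alone gave 7627 for IAA, 5788 for BAP and 82 for ACC. The mean of the 2 sets in 8 groups gave 3860 for IAA, 1756 for BAP, 1854 for ACC, 4682 for SA and 3233 for JA, where the difference between the sets no longer counts as spread. Calls against both sets numbered 484 for IAA, 200 for BAP, 62 for ACC and 1379 for SA. With only the treated and control arrays, and so fewer residual degrees of freedom, the counts were 176 for IAA, 38 for BAP, 1 for ACC, 525 for SA and 342 for JA. Own spike-in group arrays only gave 268 for IAA, 80 for BAP and 20 for ACC. Array weights gave 3628 for ACC, 8594 for SA and 5154 for JA, with weights of 3.08 and 1.34 for the control1 arrays and 0.333 and 0.259 for the control2 arrays. No filter gave 1380 for SA, with more probe sets tested.

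Leaving out each array gave 309 (without IAA replicate 1) to 2304 (without control1 replicate 2) for IAA, with 523 without IAA replicate 2, 550 without control2 replicate 1 and 623 without control2 replicate 2. It gave 75 (BAP replicate 2) to 568 (control1 replicate 2) for BAP, with 132 without BAP replicate 1 and 190 without control2 replicate 1, and 7803 to 11704 for ABA. It gave 15 (ACC replicate 1) to 455 (control2 replicate 1) for ACC, with 33 without ACC replicate 2, 47 without control1 replicate 1, 70 without control1 replicate 2 and 292 without control2 replicate 2. It gave 432 (SA replicate 1) to 2784 for SA, with 1116 without SA replicate 2 and 1405 without control1 replicate 1, and 243 (JA replicate 2) to 1786 for JA. Where 1 array of a group was left, it was assumed to vary like the other groups. The cause was not tested.

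Against the other hormones, counts with at least 2-fold change were 1577 for IAA, 1441 for BAP, 4745 for ABA, 1091 for ACC, 621 for SA and 1155 for JA. The block gave 1154 for IAA and 1726 for BAP, and the same group only gave 760 for each of these, 5522 for ACC and 5228 for JA. Array weights gave 3774 for SA. Leaving out arrays gave 1210 (IAA replicate 1) to 5771 for IAA, with 2757 without IAA replicate 2, 1105 (BAP replicate 2) to 4928 for BAP, with 2311 without BAP replicate 1, and 7470 (ABA replicate 2) to 11709 for ABA. It gave 519 (ACC replicate 1) to 2595 for ACC, with 997 without ACC replicate 2, 285 (SA replicate 1) to 1314 for SA, with 667 without SA replicate 2, and 758 (JA replicate 2) to 2857 for JA, with 1845 without JA replicate 1. Between the control sets 1750 of 5087 differed at least 2-fold, and leaving out arrays gave 1752 (control1 replicate 2) to 3679, with 2853 without control1 replicate 1 and 2040 without control2 replicate 2.

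An estimated correlation left 1 of 58 gene list shifts. Fry, which does not compare a list with other genes, gave 83 shifts, 48 of them shared with the 58. Control1 alone gave 59 (45 shared), control2 alone 56 (47), the own control set 53 (47), quantile normalization 57 (55) and the replicate block 60 (58). Same-direction overlaps summed to 3760 over 15 pairs and to 6913.5 with split controls. Of 176 named results 110 passed with only the treated and control arrays, among them 21 of 33 for IAA, 8 of 26 for BAP and 18 of 32 for JA, while 10 of 10 for ACC did not. For ACC 4 passed with its own control set and 1 with own spike-in group arrays only, where BAP had 15. Without 1 array, 13 (BAP replicate 1) and 10 (BAP replicate 2) of 26 passed for BAP, 3 (ACC replicate 1), 2 (ACC replicate 2) and 3 (control1 replicate 1) of 10 for ACC, and 16 (JA replicate 2) of 32 for JA. With the replicate block the counts were 950 for IAA, 281 for BAP, 11545 for ABA, 119 for ACC, 2175 for SA and 1416 for JA, and 171 of the 176 named results passed, all but GLU5, Lsi1 and AMT3-3 under BAP and CRSH2 and GLU5 under JA. The deviations of same-numbered arrays correlated between groups with r from -0.185 to 0.446, over 0.1 in 10 of 28 pairs of groups and in every pair among control2, ACC, SA and JA (0.107 to 0.446). Because the labels gave no pairing and not every pair of groups lay over 0.1, the numbers were not taken to pair the arrays. Within-batch comparisons were not run with the replicate number as a block, so any pairing of ACC, SA or JA with control2 was not used there.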

Other observations

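The genes in these paragraphs were chosen after their values were seen. Comparing each hormone with the other 5 was planned over all probe sets, and the tests with the spike-in group as a block were chosen after the data were seen.

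Some genes changed under several hormones against the 4 control arrays, with values in log2 units. The ammonium transporter gene AMT3-3 fell under IAA (-1.85), BAP (-1.31, within batch adjusted p = 0.115), ABA (-2.26), SA (-2.29) and JA (-1.41), and had 0.36 under ACC (limma adjusted p = 0.553). GST1 rose under IAA (2.79), ABA (2.7), SA (4.01) and JA (2.43), with 0.19 under BAP and 0.18 under ACC. OPR10, an oxophytodienoate reductase gene, rose under IAA (2.19), SA (1.72) and JA (2.24), and NAC067 under IAA (1.79), SA (1.66) and JA (1.32). Set against the mean of the other 5 hormones, AMT3-3 was higher under ACC (2.18 ± 0.24, limma adjusted p = 0.000439; with the spike-in group as a block 2.07, adjusted p = 0.00104). GST1 was lower by the same comparison under BAP (-2.23, adjusted p = 0.000111; block -1.88, adjusted p = 0.00402) and ACC (-2.24, adjusted p = 0.000255; block -2.42, adjusted p = 0.000247). Doses differed between the hormones.

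Others moved in opposite directions. RR4 rose under BAP (2.68) and fell under IAA (-1.38, within batch adjusted p = 0.0903), SA (-1.89) and JA (-1.44). EXPB11 rose under IAA (1.01, within batch adjusted p = 0.107) and BAP (1.34) and fell under ABA (-3.85) and SA (-1.85). JAZ5 rose under BAP (2.73; within batch 1.83, adjusted p = 0.0464) and JA (5.2) and fell under ABA (-1.66; against control1 adjusted p = 0.000171, against control2 0.122). Its rise under BAP did not pass with own spike-in group arrays only. The ABA arrays (2.52 and 2.89) and control2 arrays (3.78 and 3.16) lay under the floor, so the size of that fall depends on the lowest values.

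The first principal component held 43.6% of the variance, with the ABA arrays at 143 and 155 apart from the others, and the second held 24.4% and separated control1, IAA and BAP from control2, ACC, SA and JA. On the second the ABA arrays lay between these groups, at -14.2 and -18.6. None of the 64 reporter probe sets rose above the floor in any array (highest 3.99).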
